A study of Danio rerio with 6 samples.

How the data were processed

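Libraries of rRNA-depleted RNA, 6 in all, were analysed, 3 from IWR-1 and 3 from DMSO larvae, in tissue around a spinal cord transection. Groups and replicate numbers came from the sample titles, and the columns of the count table were assigned through the deposited sample sheet. Per the labels' protocols, RNA was taken with a kit made for fixed tissue and libraries were made with a directional kit. The treatment label types the dose without its prefix and the design text gives it in µm; the protocol's 35 µM is used here. Per the submitters' processing notes, cutadapt, FastQC, STAR and featureCounts were used with build GRCz11; versions and the strand setting of the counting are not given in the sources used here. Where counting ignored strand, genes that overlap on opposite strands cannot be told apart, and genes with near-identical copies can share reads.

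The deposited table holds raw counts per Ensembl gene for 22350 genes, each with at least 6 counts in some library, as the values show. The deposited comparison holds log2 fold changes with standard errors, and p-values with adjusted p-values, in columns named as DESeq2 names them per the file headers; 869 adjusted p-values there are empty. Its standard errors reach at most 0.335, so its log2 fold changes appear shrunken. The deposited normalised and rlog sheets were not used here. Gene names and coordinates came from the deposited annotation sheet.

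Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit, 2 groups of 3), which left 19562 genes; 2788 were removed as too low. Benjamini-Hochberg adjusted p below 0.05 was called. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM are TMM-scaled. Totals ran from 11014963 to 15219664 counts per library, and the common biological coefficient of variation was 17.0%. Counting intervals are at 95%, from exact binomial limits on summed counts, and the floor for a group at 0 is 3 counts over the group; both cover counting error only. The labels mention no molecular identifiers, so reads may not be independent molecules.

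38 gene lists (Wnt and other signalling, fibroblasts and matrix, neural, muscle, skin, pigment, blood, vessel and immune cell types, stress, metabolism and sample quality) were written before the data were examined, as were the tests and the alternatives, other than those stated to be chosen after seeing the data. They were tested with limma 3.58.1 camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, whose mixed test asks whether members change in either direction. Where a symbol had more than 1 gene ID the first was used. Genes named in the text follow a rule fixed with the lists: a fixed panel of 13 genes, the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 1, non-overlapping groups and an informative name, and up to 4 members of each called list with the smallest p. Genes named outside it are said to be chosen after their values were seen. Library shares were compared with exact permutation tests, and within replicate numbers with an exact paired test chosen after seeing the data.

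Samples of the same replicate number deviated together: the correlation of their deviations from the group means was 0.293, 0.341 and 0.159, all over 0.1, and every sample correlated best with its own number. The pairing comes from the data, and the labels do not say what the numbers share. Groups of 3 can be matched in few ways, so such a match can arise by chance, and this was not tested. On the second principal component the libraries of replicates 1 and 2 shared a sign. Those of replicate 3 did not (-9.33 with IWR-1, 31.5 with DMSO). Values with the number as a block are given as an alternative where they change a call or move a count by over 1.5 times. No libraries agreed within sampling noise: chi-square per degree of freedom was at least 8.72 for each pair of the same group.

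Alternatives were the replicate block, RLE and upper-quartile scaling, no filter, a filter of CPM of at least 1 in 3 samples, each library left out, mitochondrial and the 10 most abundant genes left out, counts thinned to the smallest library, DESeq2 1.42.0, limma voom with sample weights, a test against a 1.2-fold change and an adjusted p below 0.1. The limma voom sample weights were 2.90, 0.317 and 0.656 for DMSO replicates 1, 2 and 3. For IWR-1 replicates 1, 2 and 3 they were 0.631, 1.44 and 1.83. Its DMSO values therefore lean on replicate 1, and its p-values and counts are no independent support. The scripts were tested on simulated counts for this comparison, drawn from the means, spread and library sizes of its 19562 genes. Of simulated changed genes, 10.4% were recovered at 1.5-fold, 67.2% at 2-fold and 97.0% at 4-fold; 4.92% of calls were false. With no change simulated, 0 genes and 0 lists were called. Independent genes were simulated, so this says nothing of lists whose genes vary together.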

Results

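RNA was measured in trunk tissue around a spinal cord injury in wild-type (AB strain) zebrafish larvae. The cord was cut through at 5 days post fertilization, and after 6 h of recovery the larvae were kept either in 35 µM IWR-1, a small-molecule Wnt antagonist that stabilises Axin, in 0.25% DMSO, or in 0.25% DMSO alone. Tissue was collected at 3 days post injury, 8 days post fertilization. Each sample held a segment of about 1 mm from 20 animals, and each group had 3 biological replicates, 6 libraries in all. The deposited raw counts summed to between 11014963 (DMSO replicate 2) and 15219664 (DMSO replicate 3) per library over 22350 genes. The tissue is a mixture of cord, muscle, skin, notochord and connective tissue, so every value is an average over these. The 1 comparison the design gives is IWR-1 against DMSO in injured animals; no uninjured samples were analysed here.

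Along the first principal component, which held 55.8% of the variance, the 3 IWR-1 libraries lay apart from the 3 DMSO libraries. The second component (21.6%) held differences within the groups, the largest being that of DMSO replicate 2.

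**Figure D1:**
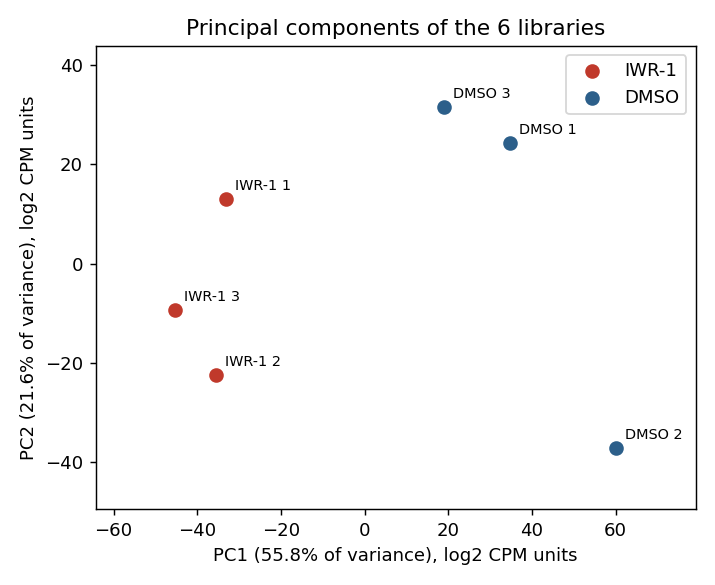
Principal components of log2 CPM over the tested genes, with 1 point per library coloured by group; axes are component scores with the percent of variance. The IWR-1 libraries lie between -45.3 and -33.0 on PC1 and the DMSO libraries between 18.98 and 60.1, with DMSO replicate 2 at -37.1 on PC2.

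With IWR-1, 12 of 22 feedback genes and targets of the Wnt pathway, 13 of 21 pigment cell genes and 21 of 50 fibroblast matrix genes fell, while 15 of 25 interferon-response genes and 7 of 41 macrophage and microglia genes rose. camera called each of these lists; with an estimated correlation the calls of the matrix (adjusted p = 0.233), interferon (adjusted p = 0.184) and macrophage (adjusted p = 0.702) lists were lost. Of 19562 genes tested with edgeR's quasi-likelihood test, 1462 changed at a Benjamini-Hochberg adjusted p below 0.05, 759 higher and 703 lower. At least 2-fold changes were found for 518 of the higher and 303 of the lower genes. The values of the groups did not overlap for 29.8% of tested genes, where chance gives 10%. Adding the replicate number as a block raised the count to 3486 (1753 higher, 1733 lower), including 1461 of the 1462. The count was 680 without DMSO replicate 1, 596 without IWR-1 replicate 2 and 447 without IWR-1 replicate 3. It was 1687 without DMSO replicate 2, the library that stood apart, and 2117 without DMSO replicate 3. The lower genes were 1082 without DMSO replicate 3 and 422 without IWR-1 replicate 1.

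The question the design poses first is whether IWR-1 lowered Wnt/β-catenin readouts in this tissue. Of 22 tested targets and feedback genes, 12 fell (15 when adjusted over the list alone), with a median log2 fold change of -0.72. The list was called lower by camera (adjusted p = 2.29e-16) and also with an estimated correlation (adjusted p = 0.0217), but with an estimated correlation and the replicate block the adjusted p was 0.253. The block gave 15 lower genes and 1 higher. notum1a, a secreted Wnt deacylase, fell from 14.0 ± 1.91 to 2.23 ± 0.44 CPM (SD, n = 3 each; log2 fold change -2.65 ± 0.21 SE, edgeR adjusted p = 7.41e-05). Its paralog notum1b fell by 2.88 on the log2 scale, and bambib, a BMP pseudoreceptor, by 1.70. The Wnt inhibitor dkk1b had 2 counts in all IWR-1 libraries together, and was 30.4-fold lower (95% counting interval 8.03 to 257). axin2 (chromosome 3, 55627948 to 55650771, GRCz11), a negative regulator of the pathway, went from 79.4 ± 9.96 to 49.7 ± 6.01 CPM (log2 fold change -0.68 ± 0.15 SE, edgeR adjusted p = 0.0211). nkd1 (chromosome 7, 37582281 to 37622370) fell by 0.71 ± 0.15 (edgeR adjusted p = 0.0168). Without DMSO replicate 1, IWR-1 replicate 2 or IWR-1 replicate 3 the edgeR adjusted p of axin2 was 0.0661, 0.111 and 0.133, and that of nkd1 0.0539, 0.0801 and 0.113. For the transcription factor genes lef1 and tcf7 the log2 fold changes were -0.62 ± 0.17 and -0.77 ± 0.26, with edgeR adjusted p of 0.0502 and 0.103; with the replicate block these were 0.0095 and 0.0393. For lef1 the adjusted p was 0.0291 with DESeq2, 0.000867 with limma voom and 0.0487 in edgeR without mitochondrial and abundant genes. The count of 12 was 7 without DMSO replicate 1, 7 without IWR-1 replicate 2 and 7 without IWR-1 replicate 3. sp5l, also on the fixed panel, was not among the tested genes.

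Among 33 Wnt ligands and receptors, 5 fell (6 adjusted over the list alone; 8 lower and 1 higher with the replicate block). These were fzd9b (-1.06), wnt5b (-1.07), fzd4 (-0.64), ror1 (-0.65) and fzd2 (-0.55), the last named after its value was seen. Without DMSO replicate 1 the edgeR adjusted p of fzd4, ror1 and fzd2 was 0.101, 0.111 and 0.104, without IWR-1 replicate 2 it was 0.120, 0.145 and 0.0962, and without IWR-1 replicate 3 it was 0.168, 0.160 and 0.143. That of wnt5b was 0.0503 without IWR-1 replicate 3, that of ror1 0.0553 without DMSO replicate 3 and that of fzd2 0.113 without IWR-1 replicate 1 and 0.0556 with counts thinned to the smallest library. The list's camera call (adjusted p = 0.0462) was lost with the replicate block (adjusted p = 0.0602) and with an estimated correlation (adjusted p = 0.233). It was also lost without DMSO replicate 1 (0.0847), DMSO replicate 3 (0.155), IWR-1 replicate 1 (0.0690) or IWR-1 replicate 2 (0.0771), and with thinned counts (0.0625). In the list of the β-catenin destruction complex and tankyrases, 0 of 19 genes passed the edgeR test, 1 had an unadjusted p below 0.05, DESeq2 called 0, limma voom 1 and the replicate block 1. For this list the median (-0.03, and 0.0038 with upper-quartile scaling) and the mean (0.01) differed in sign.

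**Figure D2:**
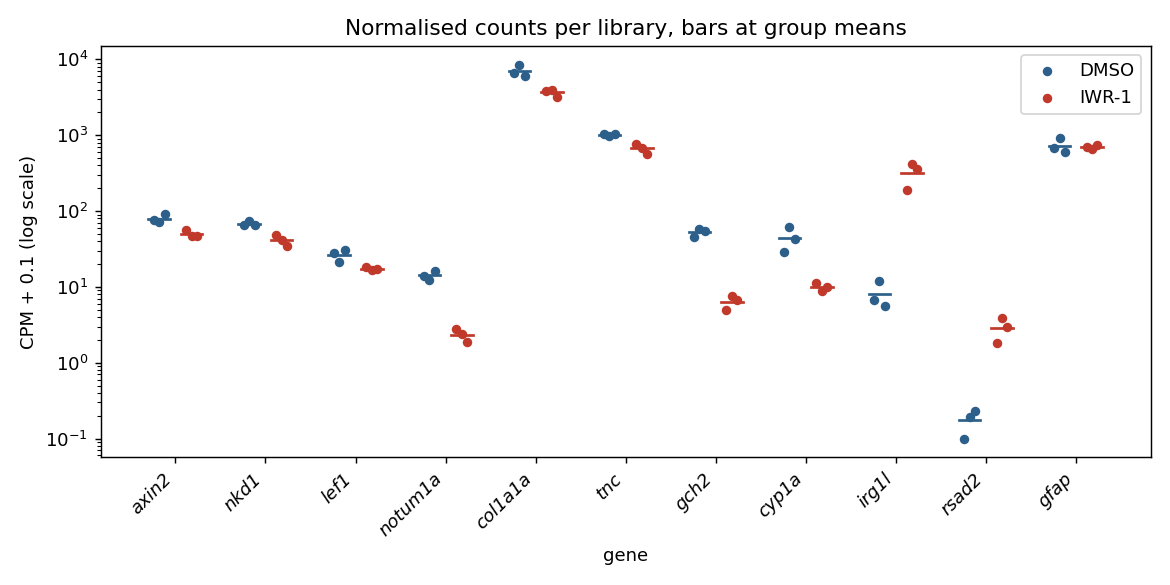
Library-size normalised counts (CPM, plus 0.1, log axis) of 11 genes in each library, with 3 points and a bar at the mean per group. For notum1a the IWR-1 mean is 2.23 and the DMSO mean 14.0 CPM; for irg1l they are 321 and 7.99; gfap, at 699 and 728, did not pass the test.

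Of 50 fibroblast matrix genes, 21 fell and 1 rose (26 and 1 adjusted over the list alone), with a median log2 fold change of -0.44. camera called the list lower (adjusted p = 1.42e-12); with an estimated correlation the adjusted p was 0.233. The 1 that rose was cthrc1b (1.86), named after its value was seen, at a DESeq2 adjusted p of 0.0597. fmoda (fibromodulin) went from 132 ± 13.0 to 53.4 ± 2.00 CPM (SD, n = 3 each; edgeR adjusted p = 0.000338). On the log2 scale col6a4a fell by 1.35 ± 0.16, serpinh1b, a collagen chaperone, fell by 0.92 ± 0.13, and lum (lumican) fell by 0.83 ± 0.13. The fibrillar collagen gene col1a1a went from 7052 ± 1294 to 3659 ± 391 CPM (SD, n = 3 each; edgeR adjusted p = 0.0105), and tnc (tenascin C) from 1016 ± 40.5 to 668 ± 99.4 CPM (edgeR adjusted p = 0.0383). Without IWR-1 replicate 3 the adjusted p of col1a1a was 0.0752; that of tnc was 0.125, 0.146 and 0.211 without DMSO replicate 1, IWR-1 replicate 2 and IWR-1 replicate 3. col12a1a (-0.26 ± 0.22), col12a1b (-0.44 ± 0.22) and pdgfrb (-0.28 ± 0.19) did not pass, at edgeR adjusted p of 0.505, 0.265 and 0.392; limma voom gave 0.0205, 0.00437 and 0.0181. fn1b was 0.49 ± 0.26 higher at an adjusted p of 0.281, and 0.0259 with the replicate block. The lower genes of the list were 9 without DMSO replicate 1, 7 without IWR-1 replicate 2 and 4 without IWR-1 replicate 3. cthrc1b was not called without DMSO replicate 1 (0.0892) or IWR-1 replicates 1, 2 and 3 (0.0537, 0.0956 and 0.116); the replicate block gave 28 lower and 2 higher.

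Of 25 fibroblast and mesenchyme identity genes, 2 fell (5 adjusted over the list alone), the paired-related homeobox genes prrx1a (-1.19 ± 0.15) and prrx1b (-1.26 ± 0.17); the median of the list was -0.13. Without DMSO replicate 1 the median was -0.04, and without IWR-1 replicates 1, 2 and 3 it was -0.25, -0.07 and -0.03. The count was 4 without DMSO replicate 2 and 3 without IWR-1 replicate 1. With the replicate block 6 fell and 1 rose. Its camera call (adjusted p = 0.0387) was lost with the block (0.0551), with thinned counts (0.0531), with an estimated correlation (adjusted p = 0.808), and without DMSO replicate 1 (0.0774), DMSO replicate 3 (0.368), IWR-1 replicate 2 (0.0887) or IWR-1 replicate 3 (0.172). In the basement membrane list 3 of 21 fell (5 adjusted over the list alone; 5 lower and 1 higher with the replicate block), nid2a (-1.02), nid1b (-0.70) and lamc3 (-0.81; camera adjusted p = 0.00454, and an adjusted p of 0.601 with an estimated correlation). Of these, nid1b and lamc3 were not called without DMSO replicate 1 (0.0878 and 0.0811), IWR-1 replicate 2 (0.0973 and 0.0998) or IWR-1 replicate 3 (0.121 and 0.118), and 5 of the list fell without DMSO replicate 2, while 1 rose without DMSO replicate 1. In the bone list 3 of 11 fell (3 adjusted over the list alone), dlx5a (-1.75), spp1 (-1.16) and dlx3b (-1.04; camera adjusted p = 0.0138, and an adjusted p of 0.233 with an estimated correlation). spp1 and dlx3b were not called without IWR-1 replicate 1 (0.0542 and 0.0536), spp1 without IWR-1 replicate 3 (0.0710) and dlx3b without IWR-1 replicate 2 (0.0782).

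Of 21 pigment cell genes, 13 fell (16 adjusted over the list alone), with a median log2 fold change of -1.25 (camera adjusted p = 1.51e-34, and an adjusted p of 0.0217 with an estimated correlation, 0.322 when the replicate block was added to the latter). gch2, which acts in pteridine synthesis, fell from 52.8 ± 6.11 to 6.31 ± 1.36 CPM (SD, n = 3 each; edgeR adjusted p = 2.77e-05). The melanin synthesis genes tyr (log2 fold change -2.14 ± 0.15), dct (-2.35 ± 0.17) and tyrp1b (-1.95 ± 0.16) fell. Without any 1 library, between 10 and 13 genes of the list were called lower.

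Of 25 interferon-response genes, 15 rose (21 adjusted over the list alone), with a median log2 fold change of 1.35. All 25 had a fold change above 0. irf7, a transcription factor of the interferon response, rose from 2.07 ± 0.57 to 13.9 ± 2.47 CPM (SD, n = 3 each; edgeR adjusted p = 0.000154). mxa rose by 2.63 ± 0.31 and the RNA sensor gene dhx58 by 2.37 ± 0.30, while rsad2 (viperin), with 3 counts in all DMSO libraries together, was 35.0-fold higher (95% counting interval 11.7 to 172). camera gave an adjusted p of 1.23e-21, and the adjusted p was 0.184 with an estimated correlation; 8 genes were called without IWR-1 replicate 2 and 8 without IWR-1 replicate 3. Of 41 macrophage and microglia genes, 7 rose (10 higher and 1 lower adjusted over the list alone; 17 higher and 1 lower with the replicate block, 28 higher with limma voom), with a median of 0.40 (0.24 without DMSO replicate 1, 0.62 without DMSO replicate 2). mpeg1.2, a perforin gene of macrophages, rose by 1.24 ± 0.20, and the leukocyte genes lcp1, ptprc and cybb by 1.05, 0.81 and 1.36. Those 3 were not called without DMSO replicate 1 (0.0550, 0.0692 and 0.0732), IWR-1 replicate 2 (0.0546, 0.0822 and 0.0721) or IWR-1 replicate 3 (0.0706, 0.0925 and 0.0754), and 1 macrophage gene was called without each of these libraries, against 12 without DMSO replicate 2. The macrophage list's camera adjusted p was 2.65e-05, and the adjusted p was 0.702 with an estimated correlation.

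In the oligodendrocyte and Schwann cell list, 4 of 18 rose (8 higher and 1 lower adjusted over the list alone, and the same numbers with the replicate block): the myelin regulator myrf (1.83 ± 0.17), and the myelin genes mag (1.03), mpz (1.17) and cldnk (0.87). camera gave an adjusted p of 2.01e-05, and the adjusted p was 0.184 with an estimated correlation. cldnk was not called without DMSO replicate 1 (0.0883), IWR-1 replicate 2 (0.0676) or IWR-1 replicate 3 (0.117). Neuron and synapse genes gave 0 of 46 past the edgeR test, 7 at an unadjusted p below 0.05, 0 with DESeq2, 7 with limma voom and 6 with the replicate block, 1 lower without DMSO replicate 2 and 1 higher without DMSO replicate 3; their median (-0.01, and 0.02 with upper-quartile scaling) and mean (0.06) differed in sign. Of 36 ependymo-radial glia and neural progenitor genes, ascl1b (ENSDARG00000009702) rose by 1.26 ± 0.21 and slc1a3b fell by 0.57 ± 0.14, both named after their values were seen (1 higher and 1 lower adjusted over the list alone, 3 and 3 with the replicate block, 2 lower without DMSO replicate 3). slc1a3b was not called without DMSO replicate 1 (0.156) or IWR-1 replicates 1, 2 and 3 (0.0561, 0.166 and 0.167). gfap, an intermediate filament gene of these glia, was at -0.06 ± 0.17 (edgeR adjusted p = 0.866). Neither list was called by camera (adjusted p = 0.839 and 0.955). Over all 19562 tested genes limma voom called 4500 and the replicate block 3486, against which the counts of these settings are to be read.

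Other lists were called lower by camera. Xenobiotic metabolism had 7 of 31 genes lower and 1 higher, the transporter gene abcb4 (1.16, named after its value was seen), and 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00073, and an adjusted p of 0.184 with an estimated correlation). In it, the aryl hydrocarbon receptor targets cyp1a (-2.15) and cyp1b1 (-2.96), the transcription factor gene foxq1a (-1.37) and the transporter gene abcb5 (-1.26) fell. abcb4 was not called without IWR-1 replicate 3 (0.0503), and 4 of the list were then lower; 2 were higher without DMSO replicate 3. Retinoic acid signalling had 5 of 18 lower (5 adjusted over the list alone), crabp2a (-1.04), crabp2b (-1.86), aldh1a2 (-0.73), dhrs3b (-0.94) and dhrs3a (-1.14, named after its value was seen); camera gave an adjusted p of 0.00282, and the adjusted p was 0.233 with an estimated correlation. aldh1a2 was not called without DMSO replicate 1 (0.0681), and aldh1a2 and dhrs3a not without IWR-1 replicate 2 (0.0750 and 0.0749) or IWR-1 replicate 3 (0.1002 and 0.0751).

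BMP and TGF-beta signalling had 4 of 31 lower (5 adjusted over the list alone, 13 lower and 1 higher with limma voom, and 1 higher without DMSO replicate 3), bmp2a (-1.26), smad6b (-0.65), fstb (-0.61) and bmp6 (-0.73), with a camera adjusted p of 0.00654 and an adjusted p of 0.365 with an estimated correlation. smad6b, fstb and bmp6 were not called without DMSO replicate 1 (0.0540, 0.0955 and 0.148), IWR-1 replicate 2 (0.116, 0.0977 and 0.171) or IWR-1 replicate 3 (0.117, 0.173 and 0.215), fstb not without IWR-1 replicate 1 (0.0629), and bmp6 not without DMSO replicate 3 (0.0636) or with upper-quartile scaling (0.0556) or thinned counts (0.0516). FGF signalling had 2 of 20 lower (3 adjusted over the list alone), fgf10a (-1.21) and fgf24 (-2.01), and 5 lower with the replicate block; the camera adjusted p was 0.0108, and the adjusted p was 0.327 with an estimated correlation. fgf10a and fgf24 were not called without IWR-1 replicate 2 (0.0540 and 0.0900) or IWR-1 replicate 3 (0.0543 and 0.108), and fgf24 not without DMSO replicate 1 (0.0515), DMSO replicate 2 (0.0548) or IWR-1 replicate 1 (0.0976). Nuclear oxidative phosphorylation had 1 of 63 lower, uqcrc1 (-0.58), 0 adjusted over the list alone (with edgeR; 20 at an unadjusted p below 0.05, 6 with DESeq2 and 6 with limma voom over all genes), 16 lower and 2 higher with the block, and 1 higher without DMSO replicate 3. uqcrc1 was not called without DMSO replicate 1 (0.0641) or IWR-1 replicates 1, 2 and 3 (0.117, 0.112 and 0.169). Its camera adjusted p was 0.00654, the adjusted p was 0.821 with an estimated correlation, and the call was lost without DMSO replicate 3 (0.288) or IWR-1 replicate 1 (0.122).

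The remaining lists that camera called were called higher. Of 17 erythrocyte genes, the globin genes hbbe2 (1.44), hbae3 (1.18) and hbbe1.3 (1.59) rose and the transferrin receptor gene tfr1a (-1.14) fell; camera gave an adjusted p of 0.00185, and the adjusted p was 0.184 with an estimated correlation. With the replicate block, as when adjusted over the list alone, 7 rose and 1 fell; hbbe1.3 was not called without IWR-1 replicate 2 (0.0607). Immediate early genes had 3 of 31 higher (3 adjusted over the list alone, 6 with the block), fosb (2.05), dusp5 (1.32) and klf2a (1.01). Their camera adjusted p was 0.0148, the adjusted p was 0.425 with an estimated correlation, and 0.134 in camera without DMSO replicate 3. klf2a was not called without DMSO replicates 1 and 3 (0.148 and 0.0576) or IWR-1 replicates 2 and 3 (0.133 and 0.203). Of 54 cell cycle genes 1 rose (1 adjusted over the list alone, 6 with the block, 17 with limma voom, 8 without DMSO replicate 3), a copy of rrm2, and the list median was 0.21, or 0.33 without DMSO replicate 3 (camera adjusted p = 0.00214, and an adjusted p of 0.808 with an estimated correlation). That rrm2 copy was at 0.107 CPM with DMSO and 6.51 with IWR-1. The other annotated copy, chosen after its value was seen, was at 20.3 and 15.8 CPM (edgeR adjusted p = 0.235). Reads shared between copies leave this rise uncertain. For cytosolic ribosomal proteins the edgeR test called 0 of 77 (0 adjusted over the list alone, 8 at an unadjusted p below 0.05, 0 with DESeq2, 30 with limma voom, 17 with the block, 17 without DMSO replicate 3), with a median of 0.19. This median was 0.09, 0.34 and 0.10 without DMSO replicate 1, DMSO replicate 3 and IWR-1 replicate 3. Their camera adjusted p was 0.00185, the adjusted p was 0.821 with an estimated correlation, and the call was lost without DMSO replicate 1 (0.103) or IWR-1 replicate 3 (0.0503).

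In all, camera called 19 of 38 lists, 7 higher and 12 lower, and 2 with an estimated correlation, pigment cells and Wnt/β-catenin targets; with the replicate block these numbers were 17 and 0. fry called 14 lists as moving on balance one way, 6 with the replicate block (pigment cells, interferon response, Wnt/β-catenin targets, xenobiotic metabolism, erythrocytes and bone), and 30 as holding changes in either direction. The mixed test looks at a list's own members only, and 4719 of 19562 genes had an unadjusted edgeR p below 0.05. The 30 lists therefore do not stand out from other genes by it. With the preset correlation of 0.01, the other 9 splits of the 6 libraries into 3 and 3 gave between 5 and 20 called lists. Of these splits, 3 gave at least 19. With an estimated correlation the highest of those other splits was 0. Each of them mixes IWR-1 and DMSO libraries, so the group difference adds to the spread within its groups. That 0 is therefore no chance level for the 2 lists called. Of the 78 genes named by the fixed rule that passed, 53 kept the call without each replicate and under the block, scaling, filter, thinning, DESeq2 and limma voom settings; genes chosen after their values were seen are not in this count.

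**Figure D3:**
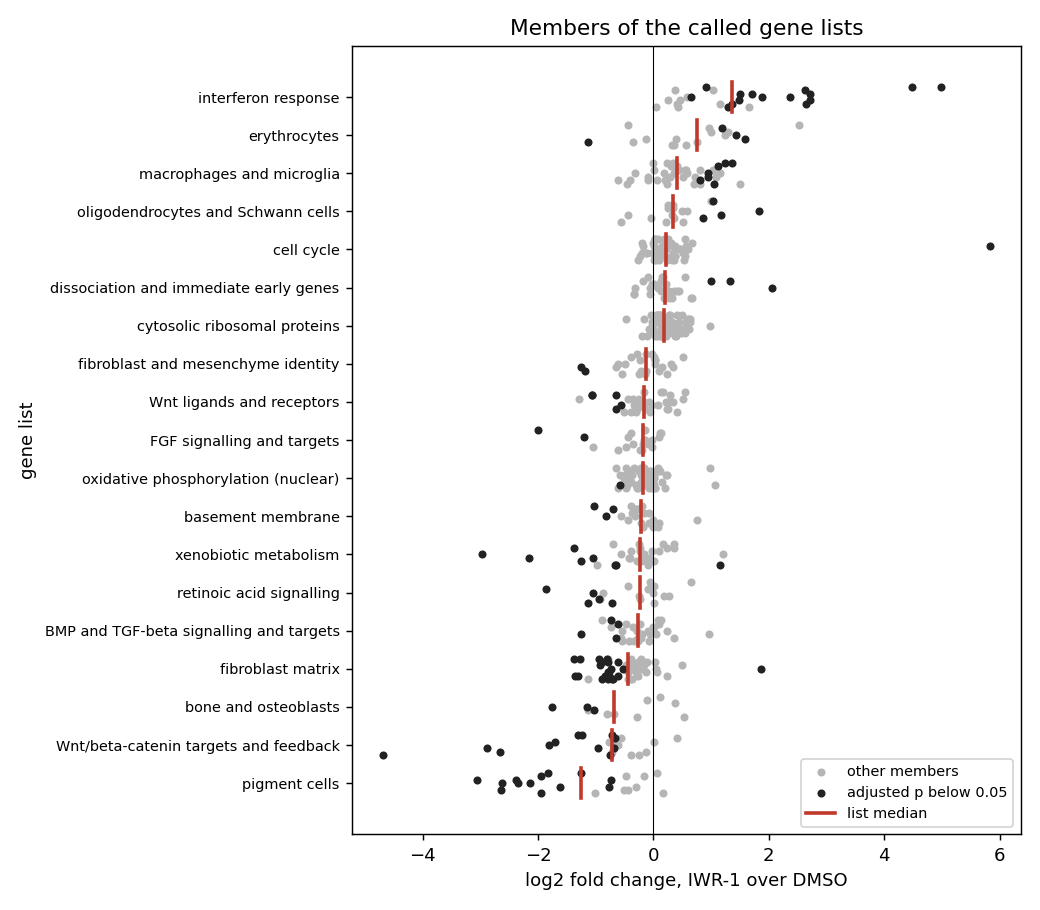
Log2 fold change (IWR-1 over DMSO) of each tested member of the 19 lists called by camera, with black points for genes at an edgeR adjusted p below 0.05, grey points for others and a red bar at the list median. Medians run from -1.25 for pigment cells to 1.35 for the interferon response.

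Among single genes, the largest rises by the fixed rule included irg1l, an immune-responsive gene, from 7.99 ± 3.34 to 321 ± 121 CPM (SD, n = 3 each; edgeR adjusted p = 2.96e-05), the mucin gene mucms1 (log2 fold change 6.34 ± 0.34) and the inducible nitric oxide synthase gene nos2a (5.95 ± 0.55). Without DMSO replicate 2 the edgeR adjusted p of nos2a was 0.0536. A copy of fgfr1bl (ENSDARG00000075027) had 0 counts in all DMSO libraries and was at least 139.5-fold higher with IWR-1, against a floor of 3 counts over the group. nuggc.3 and hao2, with 2 and 3 counts in the DMSO libraries together, were 54.0-fold (95% counting interval 14.6 to 451) and 26.0-fold (8.58 to 128) higher. fam149a rose by 4.84. rrm2 (ENSDARG00000020711) rose by 5.84 and actc1a (ENSDARG00000076126) by 4.52; their other annotated copies were at -0.36 (edgeR adjusted p = 0.235) and -0.83 (0.0130), and the other fgfr1bl copy at 0.67 (0.192, and 0.0486 with limma voom), so reads shared between copies leave these values uncertain. Without IWR-1 replicate 3 the fall of that other actc1a copy was not called (0.0878). The other copies are outside the naming rule and were chosen after their values were seen. The largest falls by the same rule were in dlx2b (-3.96), the fin-fold actinodin gene and3 (-3.57), pah (-3.30), bhlha9 (-3.19), fut9d (-3.16), dlx4a (-3.09), gch2 (-3.06), tspearb (-2.98), cyp1b1 (-2.96) and notum1b (-2.88).

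The composition of the libraries was compared with exact two-sided permutation tests, which cannot go below p = 0.1 for 3 against 3. Mitochondrially encoded genes took 10.5% ± 1.86 of counts with IWR-1 and 7.94% ± 2.18 with DMSO (SD, n = 3 each; exact p = 0.3). The share was higher with IWR-1 in all 3 pairs of the same replicate number, by 2.15, 3.37 and 2.25 percentage points (exact paired p = 0.25, the smallest possible for 3 pairs). The difference lay in mitochondrial rRNA, at 8.23% ± 1.69 and 5.62% ± 2.03 (exact p = 0.3; higher in 3 of 3 pairs, exact paired p = 0.25), while mitochondrial protein-coding genes took 2.29% ± 0.29 and 2.31% ± 0.21 (exact p = 0.8). Genes annotated as rRNA outside the mitochondria were at 0.0166% ± 0.00175 and 0.0135% ± 0.00253 (exact p = 0.1, the smallest possible). Skeletal muscle contractile genes took 23.0% ± 1.86 and 21.6% ± 0.73 (exact p = 0.4), and 25.7% ± 1.72 and 23.5% ± 1.15 of counts without mitochondrially encoded genes (exact p = 0.1, the smallest possible). The 10 most abundant genes took 26.2% ± 1.03 and 24.4% ± 0.75 (exact p = 0.2; higher in 3 of 3 pairs, exact paired p = 0.25); without mitochondrially encoded genes the remaining 7 took 19.1% ± 1.60 and 19.3% ± 1.15 (exact p = 0.8). Haemoglobin genes were at 0.00848% ± 0.00129 and 0.00351% ± 0.00035 (exact p = 0.1, the smallest possible), and gut, pancreas and liver genes at 0.00146% ± 0.00036 and 0.00296% ± 0.00117 (exact p = 0.1).

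The authors' deposited table gave 919 higher and 872 lower genes at its adjusted p below 0.05. Of the 1462 genes called with edgeR, 1407 were called in the same direction in the authors' deposited table (731 higher, 676 lower), 55 were called only with edgeR, and 384 only in the authors' deposited table, 47 of which had not been tested with edgeR. Across the tested genes, which are not independent replicates, Spearman's rho between the log2 fold changes was 0.997. A DESeq2 fit to the same counts called the same 1791 genes as the authors' deposited table.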

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

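The use of all copies of duplicated symbols in the lists, which changed no list's call, the paired test of library shares, the difference of list medians in each setting, and other places for the nfil3 family among clock genes were chosen after seeing the data; all other settings here were planned. The number of changed genes (1462; 759 higher, 703 lower) stayed within 1.5 times under RLE and upper-quartile scaling, both filters, thinning, leaving out mitochondrial and abundant genes, and DESeq2. It was 3486 (1753 higher, 1733 lower) with the replicate block, 4500 (2372 higher, 2128 lower) with limma voom and sample weights, 834 (478 higher, 356 lower) against a 1.2-fold change and 2450 (1230 higher, 1220 lower) at an adjusted p below 0.1. The last follow from the thresholds. For the block and voom the cause was not tested, and list counts in these settings are to be read against their totals over all 19562 genes. Without 1 library it ran from 447 to 2117, the higher genes from 258 to 1035 and the lower from 189 to 1082. Counts within lists that moved by over 1.5 times without 1 library or with the replicate block stand with the results, as counts or as the genes lost. With all samples limma voom, besides the counts given there, called 34 lower in the matrix list, 7 lower in identity, 9 lower in basement membrane, 5 lower in bone, 8 lower and 1 higher among Wnt ligands, 15 lower and 1 higher among Wnt targets, 5 lower in FGF signalling, 23 higher in the interferon list, 11 higher among erythrocyte genes, 10 higher and 1 lower among oligodendrocyte genes, 6 higher among immediate early genes, 10 lower and 3 higher in xenobiotic metabolism, 12 lower in the clock list, 9 higher and 11 lower in epidermis, 3 and 9 in endothelium, 9 and 3 in cytokines, 6 and 3 in neutrophils, 1 and 7 in notochord, 4 and 1 in kidney, 3 and 4 in glycolysis, 3 and 3 in radial glia, 1 and 3 in cholesterol and 1 and 2 in gut. DESeq2 called 4 lower in identity, 6 higher and 1 lower in erythrocytes, 7 and 1 in oligodendrocytes, 4 and 2 in cytokines, 4 and 2 in neutrophils, and 2 lower in notochord, glycolysis and radial glia, the last also without mitochondrial and abundant genes. Upper-quartile scaling left 2 heat shock genes lower in place of 4, and thinning gave 2 neutrophil genes higher in place of 1. The cause was not tested. Scaling moved the share of higher genes by under 10 percentage points. Called lists went from 19 to 2 with an estimated correlation, which allows for members that vary together. Among the lists that lost the call, the estimate was below the preset 0.01 for Wnt ligands and receptors (-0.0012), erythrocytes (0.00046) and bone (-0.015). Members that vary together therefore do not account for these losses, whose cause was not tested. Of the 19, 14 kept the call without each library. Of the genes and the camera calls of lists given with the results, the replicate block changed no other call than those stated there; 1461 of the 1462 genes kept the call under it. Of further genes the fixed rule names, cenpe, ttk, ier2a, rps25, rpl24 and rpl32 were called higher and twist1b, tnmd, col4a1, fgf8a, il17rd, ndufv1, cycsb and uqcrc2b lower with the block (edgeR adjusted p 0.00324 to 0.0353), and not by edgeR without it. fry called 6 lists with the block and 14 without it. gfap, not called, was at 0.0463 with limma voom and between -0.186 and 0.142 without 1 library (0.142 without DMSO replicate 2), against -0.06; the cause was not tested. Without mitochondrial genes in the denominator, the difference in the share of the 10 most abundant genes went from 1.84 to -0.28 percentage points and that of the 100 most abundant from 1.72 to 0.12, since several of these genes are mitochondrial. At this depth and with 3 replicates most small changes would be missed: 10.4% of simulated 1.5-fold changes were found.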

Other observations

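Tests in this part chosen after the result was seen are those on macrophages and their repeats in other settings, on a single IWR-1 library, on fibroblast number, with its repeats, and both on clock genes, with the versions for the nfil3 family; which patterns to weigh was also chosen then. The comparison of median differences with interquartile ranges was added once both had been seen; before it, fibroblast number had been read as excluded as the whole source. Several lists that camera did not call (adjusted p 0.0542 to 0.955) held called genes, in some of the lists in both directions. The genes named for these lists were chosen after their values were seen. In the heat shock and unfolded protein response list 6 of 33 genes rose and 4 fell (6 and 4 adjusted over the list alone, 6 and 2 with upper-quartile scaling): the chaperone genes hsp70.3 (2.82), hsp70.2 (3.16), hsp70.1 (3.69), hsp70l (1.91) and hsp90aa1.2 (1.18) were among those that rose, and the 3 numbered hsp70 genes are neighbours that can share reads. In that list 3 rose and 2 fell without DMSO replicate 1 or IWR-1 replicate 3, and 2 fell without IWR-1 replicate 2. hsp70.1 was not called without DMSO replicate 1 (edgeR adjusted p = 0.0540) or IWR-1 replicates 1 and 3 (0.0542 and 0.0531), and hsp70l not without DMSO replicates 1 and 2 (0.1002 and 0.0908) or IWR-1 replicates 1 and 3 (0.0753 and 0.0591). Among 36 epidermis genes 4 rose and 6 fell (8 and 11 adjusted over the list alone, 6 and 12 with the replicate block), including the keratin genes krt97 (-2.23), krt17 (-1.08) and krt92 (2.61), the last not called without DMSO replicate 1 (0.0980) or IWR-1 replicates 2 and 3 (0.103 and 0.110). Without DMSO replicate 1 the list had 1 gene higher and 3 lower, and without IWR-1 replicate 1 it had 5 and 3. Without IWR-1 replicate 2 or 3, 3 epidermis genes fell and the 4 rises were not called. Inflammatory cytokines had 3 of 33 higher (5 higher and 2 lower adjusted over the list alone, 6 and 4 with the block): ccl20a.3 (2.40), nfkbiaa (1.00; 0.0541 without IWR-1 replicate 3) and nfkbiab (0.84; 0.119 without DMSO replicate 1, 0.0877 and 0.174 without IWR-1 replicates 2 and 3). Without DMSO replicate 2 that list had 7 higher and 1 lower, and without DMSO replicate 3 it had 3 lower. Kidney and ionocytes had 2 of 19 higher (2 adjusted over the list alone, 5 higher and 1 lower with the block), the sodium pump genes atp1a1a.2 (1.51) and atp1b1b (1.15). Notochord and cartilage had 1 of 32 lower (1 adjusted over the list alone, 2 lower and 2 higher with the block, 2 and 1 without DMSO replicate 2, 2 lower without IWR-1 replicate 1), col9a1a (-2.07).

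In further lists most calls were lost in some fits without 1 library. Endothelium had 4 of 28 lower, cldn5b (-1.10), aqp1a.1 (-0.68), cdh5 (-0.74) and cldn5a (-0.83), and sox7 (0.72) higher (5 lower and 2 higher adjusted over the list alone, 6 and 2 with the replicate block); none of these 5 was called without DMSO replicate 1 (0.0864, 0.102, 0.115, 0.103 and 0.133) or IWR-1 replicate 3 (0.116, 0.156, 0.147, 0.191 and 0.171). Without IWR-1 replicate 2 the edgeR adjusted p of aqp1a.1, cdh5, cldn5a and sox7 was 0.116, 0.0983, 0.135 and 0.182; cldn5b and sox7 were also lost without IWR-1 replicate 1 (0.0674 and 0.0605), and sox7 without DMSO replicates 2 and 3 (0.0699 and 0.0529), with DESeq2 (0.0654), with no low-count filter (0.0502) and with thinned counts (0.0773). Glycolysis had gpib (1.29) and pfkfb3 (0.82) higher and pfkmb (-0.81) lower of 31 (2 and 2 adjusted over the list alone, 3 and 4 with the block, 2 lower without DMSO replicate 3), gpib and pfkfb3 not called without IWR-1 replicate 3 (0.0590 and 0.102), nor pfkfb3 without DMSO replicate 1 (0.0835) or IWR-1 replicate 1 (0.0817). Neutrophils had ncf1 (1.36) higher and cpa5 (-2.15) and npsn (-0.93) lower of 17 (5 and 2 adjusted over the list alone, 6 and 2 with the block), none called without IWR-1 replicate 3 (0.119, 0.121 and 0.122). ncf1 and cpa5 were also lost without DMSO replicate 1 (0.0875 and 0.0757), cpa5 and npsn without IWR-1 replicate 1 (0.0704 and 0.111), ncf1 and npsn without IWR-1 replicate 2 (0.0834 and 0.0764), and npsn without DMSO replicate 3 (0.0600). Without DMSO replicate 2 or 3, 2 neutrophil genes rose; without IWR-1 replicate 1, 6 rose and camera called the list higher (adjusted p = 0.00936, list median 0.41). Skeletal muscle had myhz1.2 (0.62) higher and myhb (-0.80) lower of 49 (7 and 3 with the block; 0 adjusted over the list alone with edgeR, 12 at an unadjusted p below 0.05, 3 with DESeq2 and 11 with limma voom over all genes), neither called without IWR-1 replicate 3 (0.197 and 0.142), DMSO replicate 1 (0.120 and 0.103) or IWR-1 replicates 1 (0.106 and 0.0718) and 2 (0.0653 and 0.0796); without DMSO replicate 3 the list had 4 higher and 2 lower. Cholesterol biosynthesis had srebf2 (0.57) higher of 27 (1 adjusted over the list alone, 1 higher and 4 lower with the block), not called without DMSO replicate 1 (0.104) or IWR-1 replicates 2 and 3 (0.0822 and 0.140); without DMSO replicate 3, 3 of that list fell. Of 26 Nrf2 targets hmox1a (1.62) was higher (0 adjusted over the list alone with edgeR; 4 at an unadjusted p below 0.05, 0 with DESeq2 and 4 with limma voom over all genes; 1 higher and 2 lower with the block, 1 lower without IWR-1 replicate 2). Its adjusted p was 0.197 with the block, 0.0654 with DESeq2, 0.0579 with limma voom, 0.0567, 0.221 and 0.0669 without DMSO replicates 1, 2 and 3, and 0.126 and 0.170 without IWR-1 replicates 2 and 3. Gut, pancreas and liver had cpb1 (-1.39) lower of 8 (1 adjusted over the list alone, 2 lower and 1 higher with the block, 1 higher without DMSO replicate 3), at an adjusted p of 0.144 and 0.104 without DMSO replicates 1 and 2, 0.104, 0.149 and 0.202 without IWR-1 replicates 1, 2 and 3, 0.108 with DESeq2, 0.0505 and 0.0519 with RLE and upper-quartile scaling, and 0.0564 with no low-count filter. With edgeR, 0 of 22 myogenic, 0 of 16 Hedgehog and 0 of 13 mitochondrially encoded genes passed, also when adjusted over the list alone, with 7, 2 and 1 at an unadjusted p below 0.05; DESeq2 called 0 in each, limma voom 6, 3 and 1, and the replicate block 1, 0 and 2. Without DMSO replicate 2, edgeR called 1 myogenic and 1 Hedgehog gene lower, and without DMSO replicate 3 it called 1 mitochondrially encoded gene higher and 1 lower. The median and mean of the mitochondrially encoded list (0.03 and -0.06) differed in sign, and those of glycolysis (0.01 and 0.00152) lay above 0 where camera's direction was down.

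Several of these lists were called by camera in some other settings. The heat shock list was called higher with a filter of CPM of at least 1 (camera adjusted p = 0.0498) and without DMSO replicate 2 (0.0184), IWR-1 replicate 2 (0.0330) or IWR-1 replicate 3 (0.0308), and the kidney list with that filter (0.0477) and without DMSO replicate 2 (0.0192) or IWR-1 replicate 3 (0.0413). fry also called both higher (adjusted p = 0.0214 and 0.0111; 0.122 and 0.0938 with the replicate block). The gut, pancreas and liver list was called lower with no low-count filter (0.0335) and without IWR-1 replicate 2 (0.0425), and the myogenic list with no low-count filter (0.0446) and without DMSO replicates 1 and 2 (0.0486 and 0.00874) or IWR-1 replicate 1 (0.0276). Without DMSO replicate 2 or IWR-1 replicate 1 the notochord (0.0202 and 0.00321) and endothelium lists (0.00854 and 0.0294) were called lower, as was the epidermis list without IWR-1 replicate 3 (0.0413). With all samples and an estimated correlation, the adjusted p of these lists and of neutrophils lay between 0.233 and 0.980.

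Of the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, the real one gave 1462 changed genes and was the 1 split with as many; the highest other gave 0 by edgeR, with up to 1475 genes at an unadjusted p below 0.05. The other splits mix IWR-1 and DMSO libraries, so the group difference adds to their spread, and their 0 genes give no chance level. For lists called by camera the real split gave 19 and the highest other 20, and 4 of the 10 gave as many as the real one. Among the other splits that part all 3 pairs, as the real one does, the highest was also 20 lists.

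Of 25 interferon-response genes 15 rose with IWR-1 (the list's adjusted p = 0.184 with an estimated correlation). More macrophages in the tissue would raise macrophage genes as much. The interferon median exceeded the macrophage median by 0.949 (95% bootstrap interval over genes 0.298 to 1.40), more than the interquartile range of 0.614 among macrophage genes. Over the other settings the lower bounds ran from 0.0405, with limma voom, to 0.533. The bootstrap draws genes as if independent, while estimated correlations were 0.41 among interferon and 0.704 among macrophage members. Of the macrophage members 34 lay above 0 and 7 below. Those with the smallest p, mpeg1.2, lcp1, ptprc and cybb, rose by 1.24, 1.05, 0.81 and 1.36, against an interferon median of 1.35. The interferon genes with the smallest p, irf7, mxa, rsad2 and dhx58, rose by 2.71, 2.63, 4.98 and 2.37. Of these, rsad2 had 3 counts in all DMSO libraries together. Both sets of genes were picked by p, and members of both lists vary together. Neither the medians nor these genes therefore decide whether macrophage number was the whole source. A single IWR-1 library was not the source, since the lowest IWR-1 library lay 0.701 above the highest DMSO library on the log2 scale, beyond the largest SD within a group of 0.406. An effect of the treatment may underlie it, as a hypothesis. Macrophage number stays open. A change in the state of macrophages, or an infection shared by the treated dishes, also stays open and was not tested.

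Of 50 fibroblast matrix genes 21 fell with IWR-1 and 1 rose. Leaving out any 1 DMSO library left the matrix median at or below -0.382 and the list called (camera adjusted p at most 1.61e-08). The lower median thus did not rest on 1 DMSO library. The camera call adds little, since with all samples and an estimated correlation the list's adjusted p was 0.233. Without DMSO replicate 1 the lower genes were 9, against 21. On the log2 scale, library medians over the DMSO mean were -0.318, -0.51 and -0.625 with IWR-1 and 0.0455, -0.161 and 0.117 with DMSO. Fewer fibroblasts would lower identity genes as much, and the identity median lay 0.304 above the matrix median (95% bootstrap interval 0.143 to 0.642; lower bounds of 0.0542, without IWR-1 replicate 1, to 0.175 over the other settings). But identity genes went both ways, 15 below 0 and 10 above, with an interquartile range of 0.422 that exceeds this difference, prrx1a (-1.19) and prrx1b (-1.26) fell by more than the matrix median, and camera called the identity list lower (adjusted p = 0.0387, and an adjusted p of 0.808 with an estimated correlation). Since these members decide it neither way, fewer fibroblasts and reduced matrix expression under the treatment cannot be told apart.

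Clock genes of different families moved apart: the 33 tested members of the list, all fixed beforehand, were assigned by family, after their values had been seen, to a side with the arntl, clock, npas2, ror and nfil3 families (6 of 12 rose, median 0.51) and a side with all others, such as per, cry and dbp (6 of 21 fell and 1 rose, median -0.34). The list gave 7 higher and 6 lower (8 and 11 adjusted over the list alone, 7 and 10 with the replicate block), and 3 to 6 higher and 3 to 8 lower without any 1 library. The medians differed by 0.844 (95% bootstrap interval over genes 0.453 to 1.29), by 1.00 (0.538 to 1.35) in a first version that left out 6 members, and, since nfil3 is a repressor, also by 0.73 (0.232 to 1.12) without its family and 0.61 (0.203 to 1.07) with it on the other side. The lowest IWR-1 library lay 0.58 above the highest DMSO library (0.369 without the nfil3 family and 0.216 with it moved), against a largest SD within a group of 0.173 (0.189 and 0.161), so a single library was not the source. Collection at different times of day may give such a pattern and cannot be told apart from an effect of IWR-1, because the labels give no time of day and the groups do not overlap.

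Genes that rose lay next to one another more often than chance gives, a hypothesis tested with shuffled calls: 99 neighbouring pairs were both higher, against a mean of 26.6 and a highest value of 49 in 10000 shuffles (permutation p = 1e-04, the smallest they can give), and 37 pairs were both lower (mean 22.9, permutation p = 0.002). The longest runs, 7 genes with histone genes among them on chromosome 7 and 6 genes with irg1l on chromosome 14, include members of gene families, which may share reads, so the 99 pairs are not independent events. A run of 4 higher genes on chromosome 19, named after their values were seen, was tapbp.2, psmb8a, psmb13a and psmb12. The psmb genes among them are on the interferon list, so that list's called genes are not all independent either. The cause of the runs was not tested.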
